A study of Mus musculus with 30 samples.

How the data were processed

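The deposited processed table of the series was analysed without its publication. It holds 1 value per probe and array for 6267 probes on 30 2-colour arrays of spotted 70-mer oligonucleotides. Per the labels, gland RNA was labelled with Cy5 and RNA from a common mouse reference with Cy3, after CsCl ultracentrifugation and an amplification step in the deposited protocols. The authors deposited linear ratios, and the values were taken as gland over reference. That direction is likely but not written in the file. Its basis is the dye assignment in the labels and the very high values of the milk protein genes Lalba and Csn3 in lactating glands. Scanner, background correction, normalization and filtering are not given in the sources used here.

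Ratios listed at 0 (13146 values) or 0.01 (1223 values), together 7.64% of the table, were taken as missing, because no value lies between them and the meaning of neither is given in the sources used here. The design, written before the data were examined, assumed log2 ratios unless the table held linear ones; it holds linear ratios, and these were log2 transformed. The array medians of the ratio ran from 0.804 to 1.08, a spread over 0.1 on the log2 scale, so each array was centred on its median by a rule written before the data were examined. A probe was tested if it had a value on at least 2 of the 3 arrays of every group. That left 5010 probes, 3968 of them measured on all 30 arrays, and set aside 1257.

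Probes were named from the deposited platform table: 3997 carry 1 gene symbol, 115 carry several and 2155 carry none. Of the tested probes, 3160 have 1 symbol and 1850 have none or several. Probes without a single symbol were tested and counted but not named. No genome build is named, so no coordinates are given. Lyz1 and Lyz2 are close paralogs, and a 70-mer may not separate them. On 106 of 3861 probes with at least 10 ratios from 1 to 100, at least 90% of those ratios were whole multiples of 0.1 (tolerance 1e-06 of that step), as if the reference signal were at a fixed lowest value. Igfbp5, Tmprss2, Retnla, Slc28a3, Folr1, Lum, Hpgd, Cyp27a1, Slc13a2 and Ly86 are among them, and their ratios are bounded by that value.

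Differences were tested with limma 3.58.1 in R 4.3.3 (Python 3.11.15, pandas 2.3.3, numpy 2.4.6, matplotlib 3.10.9 for tables and figures). A single linear model with 1 mean for each of the 10 groups gave 20 residual degrees of freedom. Each day was compared with lactation within a genotype, E2F3 +/- with wild type at each time and over all times, and the 2 responses with each other (genotype by time). F tests covered the 4 day contrasts jointly. A probe passed at a Benjamini-Hochberg adjusted p under 0.05 over all tested probes. Errors after ± are standard errors of the log2 difference from this model unless SD is written, and n counts arrays with a value. Each array is a separate mouse per the labels, so the p values reflect mouse-to-mouse variation, and 3 mice per group limit the precision.

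The named genes follow a rule written before the data were examined. It takes every E2f probe, the largest passing changes at days 1 and 4 in each genotype with all 3 arrays beyond the 3 lactation arrays, the largest passing genotype differences at each time, the 6 strongest genotype by time probes, and the strongest members of gene lists. For genes taken from lists, the probes of a gene were averaged.

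In all, 30 gene lists were written before the data were examined. They cover milk proteins, milk lipid synthesis, cholesterol synthesis, prolactin and Stat5, Stat3 and LIF, acute phase, apoptosis, lysosome, matrix proteases, TGF-beta, E2F targets, mitosis, the E2F and retinoblastoma family, interferon, MHC class II, unfolded protein response, immediate early genes, oxidative phosphorylation and ribosomal proteins. The cell type lists are luminal epithelium, myoepithelium, adipocytes, fibroblasts, macrophages, neutrophils and eosinophils, T and NK cells, B and plasma cells, endothelium, skeletal muscle and red blood cells. Camera with a preset correlation of 0.01 was run on 2287 genes measured on all arrays, for the 19 lists with at least 5 such genes. It was repeated with the correlation estimated from the data. Members were counted among 2901 tested genes, adjusted over all of these and again adjusted over the list alone. No member of the neutrophil and eosinophil list or of the red blood cell list was tested.

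An involution score placed each array on the line from the mean of the 6 lactation arrays (0) to the mean of the 6 day 4 arrays (1), over the probes measured on all arrays. Genotypes were compared by permutation within times (100000 reassignments) and by an exact test at each time, whose smallest possible p with 3 against 3 is 0.1.

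The model ran on simulated data of this layout, 50 probes changed per fold. Of probes changed 1.5-, 2-, 4- and 8-fold it recovered 4%, 38%, 96%, 94% for wild type day 4 against lactation, 10%, 36%, 80%, 92% for genotype at day 2, 2%, 12%, 64%, 86% for genotype by time and 0%, 0%, 14%, 52% over all times when only day 2 was changed. At most 11 of 4810 unchanged probes were called, but 460 in a mixed split of real day 4 arrays. Small changes are mostly missed.

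Alternatives set before the data were examined were values as deposited, quantile normalization, other filters, array quality weights, a robust prior, only the groups compared, replicate number as a block, and leaving out each array in turn. Added after the data were seen were a floor of 0.1 with all probes tested, a median over the probes on all arrays, leaving out the 3 arrays of lowest quality weight, cameraPR on every tested gene, a skeletal muscle covariate, and a contrast of the day 2 genotype difference with the other 4 times. Replicate numbers were checked for pairing between groups: in 0 of 13 comparisons were all 3 pairs correlated above 0.1, so no pairing was used.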

Results

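Mammary glands of wild type and E2F3 +/- mice were taken at lactation (involution day 0) and at days 1, 2, 3 and 4 of involution, the regression of the milk-producing gland. E2F3 is a transcription factor that drives genes of cell cycle entry. The targeted gene could not be read out, because 0 probes are named E2f3. Its relative E2f1, also a driver of S phase genes (probe M300005663), did not differ by genotype at lactation (log2 0.09 ± 0.39, adjusted p = 0.998). On days 1 to 4 the E2f1 difference was 0.36, -0.08, -0.31 and 0.58 (adjusted p = 0.852, 0.910, 0.719 and 0.574), and over all times 0.13 ± 0.19 (adjusted p = 0.840). Here and throughout, values after ± are standard errors from limma, adjusted p values are from limma unless camera is named, and n = 3 and 3 unless given. Largest changes against lactation are ranked among passing probes with 1 gene symbol whose arrays all lie beyond those of lactation. For E2f1 at day 4, n = 2 and 2.

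E2f1 fell with involution in wild type glands. The change was -1.07 ± 0.39 at day 2 (adjusted p = 0.0219), -1.21 ± 0.39 at day 3 (adjusted p = 0.0191) and -1.75 ± 0.44 at day 4 (adjusted p = 0.00265, n = 2 and 3). Day 1 did not pass (-0.91 ± 0.39, adjusted p = 0.0745). The day 2 call was lost without wild type day 2 replicate 3 (adjusted p = 0.150), wild type lactation replicate 1 or 3. The day 3 call was lost without wild type day 3 replicate 2 (adjusted p = 0.152), wild type lactation replicate 1 or 3. The day 4 call was lost without wild type day 4 replicate 3 (adjusted p = 0.0514).

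The first principal component of the arrays held 48.8% of the variance and the second 17.7%. By correlation over probes, which are not independent replicates, 22 of 30 arrays lay closest to the mean of their own group and 23 to a group of their own time. Wild type day 2 replicate 3 was nearer to E2F3 +/- day 4 (r = 0.867) than to its own group (r = 0.495). E2F3 +/- day 4 replicate 3 (r = -0.0363 to its own group) was nearest to wild type day 3 (r = 0.376).

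Genes of milk fat synthesis fell within the first day of involution in wild type glands. Fabp3, the fatty acid carrier of lactating epithelium (probe M200004322), fell 69.5-fold (log2 -6.12 ± 0.71, adjusted p = 4.53e-07). The desaturase Fads1 (53.1-fold, log2 -5.73 ± 0.35), the medium-chain thioesterase Olah (40.8-fold) and the carboxylase Acacb (35.3-fold) fell with it. So did the bone morphogenetic protein antagonist Chrdl2 (35.7-fold) and the nucleoside carrier Slc28a3 (31.0-fold). Of 22 milk lipid genes, 0 were higher and 19 lower, with mean log2 -3.34. Camera on milk lipid genes gave adjusted p = 2.36e-13, adjusted p = 0.00420 with an estimated correlation. The elongase Elovl5 (-4.38 ± 0.24), the phosphatase Lpin1 (-4.64 ± 0.36) and the lipase Lpl (-3.99 ± 0.36) led them. Of 7 cholesterol synthesis genes, 0 were higher and 7 lower, with mean log2 -1.62. For cholesterol synthesis genes camera adjusted p = 9.63e-04, adjusted p = 0.191 with an estimated correlation. Mvd of the mevalonate pathway changed by -2.71 ± 0.36.

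Among probes with a gene symbol, the largest increases at day 1 were in the acute phase carrier Orm2 (79.8-fold, log2 6.32 ± 1.201) and the metal-binding Mt2 (55.7-fold, log2 5.80 ± 0.57). The membrane protein Basp1 (30.9-fold), the lipopolysaccharide receptor Cd14 (30.5-fold) and the cathepsin Ctsl (27.3-fold) followed. Igfbp5, a binder of survival factors that rises as alveoli regress, rose 24.1-fold (n = 3 and 2). Of 9 acute phase genes, 7 were higher and 0 lower (8 and 0 adjusted over the list alone), with mean log2 3.11. The acute phase list had camera adjusted p = 0.00930, adjusted p = 0.256 with an estimated correlation. Haptoglobin, Hp (3.09 ± 0.67), is among them. Keratins and junction genes of the luminal epithelium rose too: Krt8 (3.17 ± 0.37), Krt18 (2.75 ± 0.38), Krt7 (3.22 ± 0.45) and Cldn3 (3.92 ± 0.74). Of 10 luminal genes, 7 were higher and 0 lower (8 and 0 adjusted over the list alone), with mean log2 2.10. Camera on luminal genes gave adjusted p = 0.00930, adjusted p = 0.306 with an estimated correlation.

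The prolactin effectors Stat5a (-2.62 ± 0.30) and Stat5b (-1.51 ± 0.31) fell at day 1, while Osmr, a receptor for the Stat3 activator oncostatin M, rose by 2.75 ± 0.31 (n = 3 and 2). Of 7 prolactin and Stat5 genes, 1 was higher and 4 lower, with mean log2 -0.78. For prolactin and Stat5 genes camera adjusted p = 0.0259, adjusted p = 0.131 with an estimated correlation. Respiratory chain genes such as Atp5g1 (-1.36 ± 0.31) fell. Of 25 oxidative phosphorylation genes, 0 were higher and 9 lower (0 and 12 adjusted over the list alone), with mean log2 -0.83. The oxidative phosphorylation list had camera adjusted p = 8.93e-04, adjusted p = 0.686 with an estimated correlation.

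Macrophage genes rose from day 2 in wild type glands. The lysozymes Lyz2 (4.73 ± 0.65) and Lyz1 (4.29 ± 0.60) and the receptor chains Fcer1g (3.50 ± 0.49) and Tyrobp (2.69 ± 0.27) led at day 2. The scavenger receptor Cd68 (3.20 ± 0.42) and the pore former Mpeg1 (2.89 ± 0.47) were among those higher at day 4. Of 11 macrophage genes, 1 was higher at day 1, 11 at day 2, 10 at day 3 and 11 at day 4, the same adjusted over the list alone. Their mean log2 change was 2.90 at day 2 (camera adjusted p = 8.51e-04, adjusted p = 0.431 with an estimated correlation). At day 3 it was 2.34 (camera adjusted p = 1.83e-04, adjusted p = 0.243 with an estimated correlation) and at day 4 2.79 (camera adjusted p = 4.53e-04, adjusted p = 0.339 with an estimated correlation).

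Lysosomal genes rose over the days. Of 21, 4 were higher and 1 lower at day 1 (camera adjusted p = 0.248) and 11 were higher and 2 lower at day 2 (camera adjusted p = 0.0622), the same adjusted over the list alone. The cathepsins Ctsl (2.99 ± 0.41) and Ctss (2.56 ± 0.48) were higher at day 3, and the protease Lgmn (2.97 ± 0.36) and Laptm5 (3.24 ± 0.46) at day 4. Of 21 lysosome genes, 14 were higher and 1 lower (15 and 1 adjusted over the list alone) at day 3, with mean log2 1.17. Camera on lysosome genes gave adjusted p = 2.85e-04, adjusted p = 0.0922 with an estimated correlation. At day 4, 14 were higher and 2 lower (15 and 3 adjusted over the list alone), with mean log2 1.198 (camera adjusted p = 4.53e-04, adjusted p = 0.156 with an estimated correlation).

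Matrix genes of fibroblasts rose from day 2, led by the proteoglycan Dcn (2.57 ± 0.30) and the receptor Pdgfra (2.51 ± 0.40). Of 20 fibroblast genes, 17 were higher and 1 lower at day 2, with mean log2 1.53. For fibroblast genes camera adjusted p = 0.00764, adjusted p = 0.583 with an estimated correlation. At day 3, 13 were higher and 1 lower (15 and 1 adjusted over the list alone) (camera adjusted p = 0.00625, adjusted p = 0.586 with an estimated correlation). At day 4, 15 were higher and 1 lower (camera adjusted p = 0.00495, adjusted p = 0.484 with an estimated correlation). Skeletal muscle genes moved with them. Of 9, 9 were higher at day 2 (mean log2 4.08), 4 at day 3 (2.73) and 9 at day 4 (4.15), the same adjusted over the list alone. The muscle proteins Eno3 (40.4-fold), Actn3 (24.7-fold, n = 3 and 2), Myh2 (24.0-fold, n = 3 and 2) and Ak1 (22.1-fold, n = 3 and 2) are among the largest increases at day 4. Actn3 lost its call without wild type lactation replicate 3 (adjusted p = 0.132). With the muscle list as a covariate, 1996 probes pass at day 2 and 1541 at day 4.

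By day 4 Igfbp5 (48.5-fold, log2 5.60 ± 0.69, n = 3 and 2) and Retnla, a product of alternatively activated macrophages (25.8-fold), were also among the largest increases. The largest decreases were in Shisa9 (84.0-fold, log2 -6.39 ± 0.87), the disulfide maker Qsox1 (67.4-fold) and the nucleotide enzyme Prps2 (61.2-fold). Fabp3 (59.8-fold), the chromatin reader Brpf1 (47.2-fold) and the potassium channel Kcnj6 (40.3-fold) followed. Of the fat cell genes, Fabp4 (2.75 ± 0.51) rose at day 2 and Pck1 (4.00 ± 0.73) at day 4, while the fatty acid carrier Cd36 (-2.85 ± 0.33) was lower at day 1.

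Milk protein genes fell by day 2, led by the fat globule enzyme Xdh (-4.04 ± 0.61), the folate receptor Folr1 (-4.47 ± 0.74) and the casein Csn3 (-2.70 ± 0.49). Of 7 genes, 1 was higher and 3 lower (1 and 4 adjusted over the list alone) at day 1. At day 2, 0 were higher and 6 lower (camera adjusted p = 0.00607, adjusted p = 0.431 with an estimated correlation). At day 3, 0 were higher and 2 lower, and at day 4, 0 were higher and 6 lower (camera adjusted p = 0.0242, adjusted p = 0.484 with an estimated correlation). Without wild type day 4 replicate 2 the day 4 calls of the list and Xdh were lost (adjusted p = 0.0790 and 0.0941). Milk lipid genes stayed low. On day 2, 2 were higher and 17 lower (camera adjusted p = 1.71e-05, adjusted p = 0.187 with an estimated correlation). On day 3, 0 were higher and 18 lower (0 and 19 adjusted over the list alone) (camera adjusted p = 1.48e-08, adjusted p = 0.0359 with an estimated correlation). On day 4, 2 were higher and 13 lower (2 and 15 adjusted over the list alone) (camera adjusted p = 4.53e-04, adjusted p = 0.156 with an estimated correlation).

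All 7 cholesterol genes, with Sqle (-3.39 ± 0.35) in the lead at day 2, were lower on each later day. On days 2, 3 and 4 camera adjusted p = 8.51e-04, 2.78e-05 and 4.53e-04, and adjusted p = 0.268, 0.0875 and 0.156 with an estimated correlation. Of the acute phase genes at day 3, 8 were higher and 0 lower (camera adjusted p = 0.00940, adjusted p = 0.243 with an estimated correlation), with Saa2 (5.06 ± 0.99) in front. They counted 6 higher and 1 lower at day 2 and 5 higher and 0 lower at day 4, without a camera call. Respiratory genes at day 3 counted 0 higher and 5 lower (camera adjusted p = 0.0437, adjusted p = 0.586 with an estimated correlation), a call lost without any array but wild type lactation replicate 1 and wild type day 3 replicate 2 (adjusted p up to 0.0741). Ribosomal proteins, which set translation capacity, fell at day 4, with Rpl8 (-0.67 ± 0.15) lower and Rpl22 (1.93 ± 0.36, n = 3 and 2) higher. Of 20 ribosomal genes, 1 was higher and 10 lower, with mean log2 -0.52. The ribosomal list had camera adjusted p = 0.00442, adjusted p = 0.484 with an estimated correlation.

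Against lactation, 1839 of 5010 probes passed, 926 higher and 913 lower, at day 1 in wild type glands. At day 2 it was 3267 (1592 higher and 1675 lower), at day 3 1954 (873 and 1081) and at day 4 2825 (1274 and 1551). As deposited, without centring, the larger share is higher on each day, with 1105 of 1832, 1868 of 3383, 1112 of 2027 and 1552 of 2888 on days 1 to 4. The F test over the days passed 4108. All 4 days passed for 897 probes. Of 1173 passing at days 1 and 4, 1144 kept their direction. Whole-gland RNA does not separate a change within cells from a change in cell types. Array quality weights raise the counts to 3005 at day 1 and 3487 at day 3, and day 3 gives 3209 with only the groups compared.

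**Figure D1:**
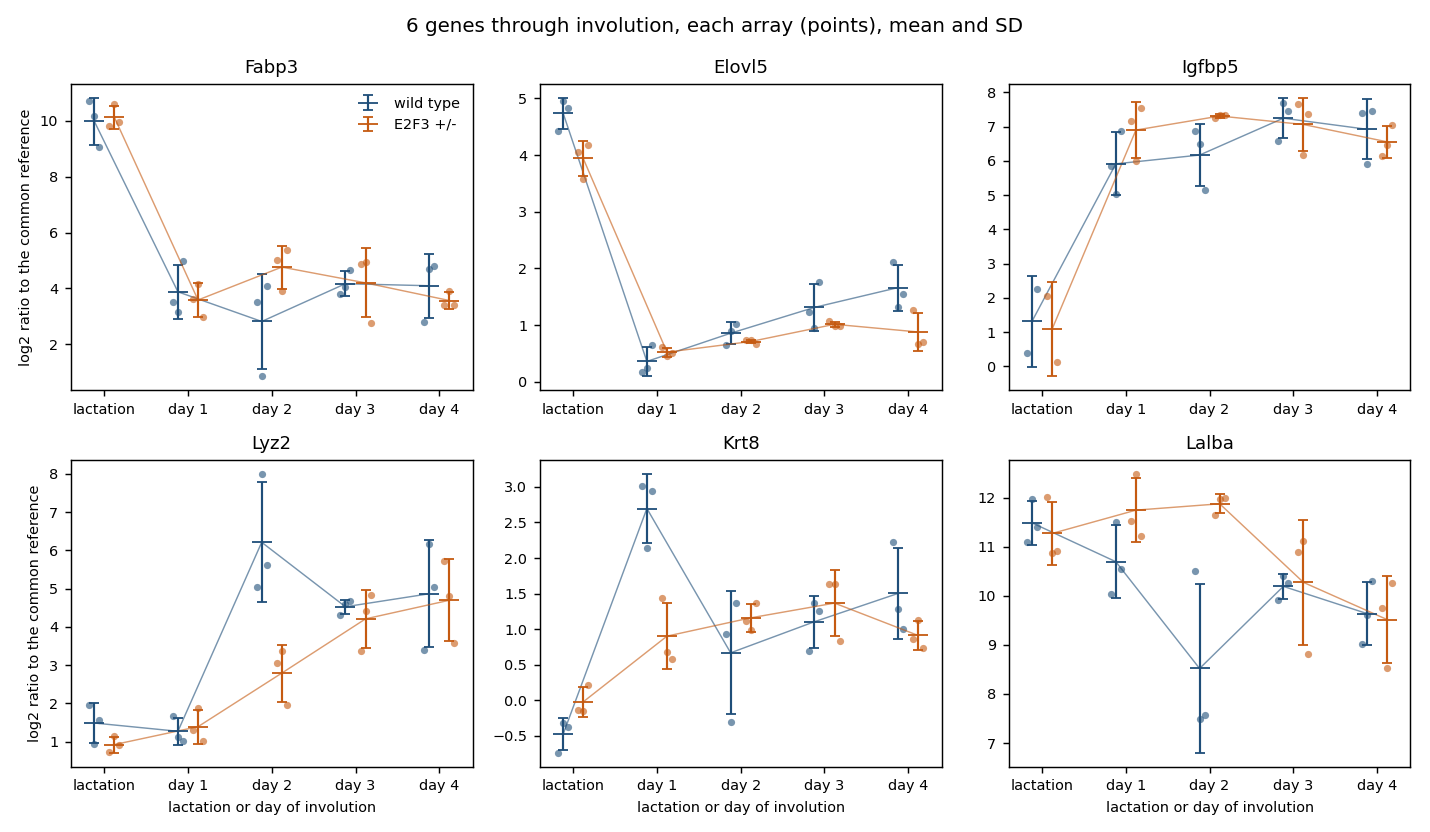
Log2 ratio to the common reference (vertical) at lactation and days 1 to 4 of involution (horizontal) for Fabp3, Elovl5, Igfbp5, Lyz2, Krt8 and Lalba in wild type and E2F3 +/- glands, with a point per array and the mean and SD of 3 (2 for Igfbp5 at lactation). Fabp3 falls by day 1 in both genotypes, and at day 2 Lyz2 is 10.7-fold lower and Lalba 10.3-fold higher in E2F3 +/- glands.

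**Figure D2:**
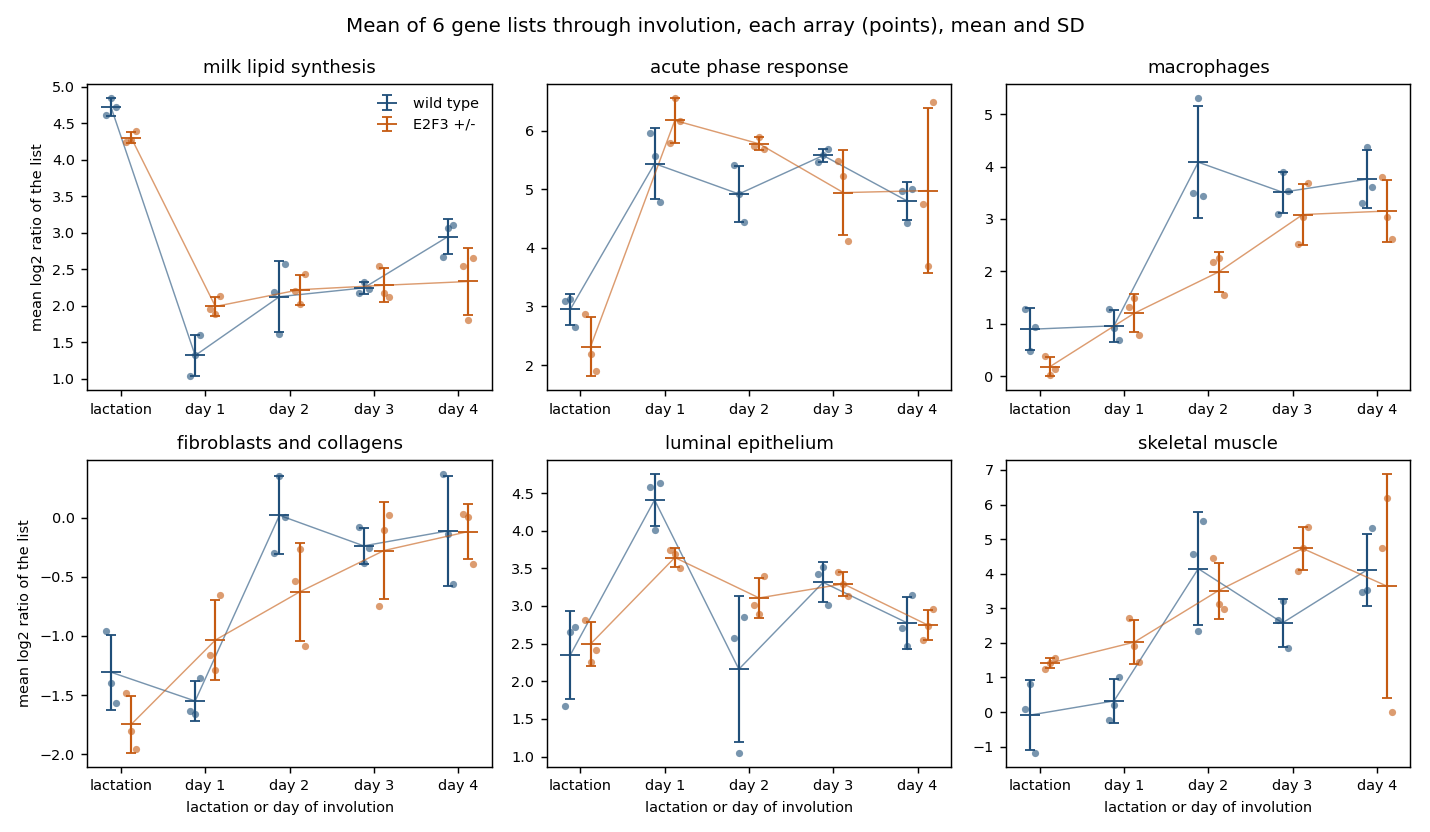
Mean log2 ratio of the list members measured on all arrays (vertical) at lactation and days 1 to 4 of involution (horizontal) for 6 gene lists in wild type and E2F3 +/- glands, with a point per array and the mean and SD of 3. Milk lipid genes fall by day 1, in wild type glands macrophage genes rise from day 2, and the skeletal muscle panel holds only 3 genes, fewer than the 9 tested.

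E2F3 +/- glands passed through involution with many of the same genes. At day 1 the serum amyloids Saa2 (269.9-fold, log2 8.08 ± 1.11, n = 3 and 2) and Saa1 (107-fold), with Orm2 (149-fold, n = 3 and 2) and Cd14 (59.1-fold), rose most. Saa2 had adjusted p = 7.09e-06. Fabp3 (93.9-fold, log2 -6.55 ± 0.71), Olah (60.0-fold), the glycine decarboxylase Gldc (25.8-fold) and the polyamine enzyme Odc1 (18.3-fold) fell most. At day 4 Saa2 (58.0-fold, log2 5.86 ± 1.11, n = 3 and 2), Igfbp5 (44.0-fold, n = 3 and 2), Retnla (29.97-fold) and the channel regulator Clca3b (26.0-fold, n = 3 and 2) were highest. Qsox1 (297-fold, log2 -8.21 ± 0.76), Olah (282-fold), Fabp3 (95.1-fold) and Shisa9 (77.7-fold) were lowest. E2f1 fell at day 2 (-1.24 ± 0.39), day 3 (-1.62 ± 0.39, adjusted p = 0.00178) and day 4 (-1.26 ± 0.44, n = 2 and 3). Its day 3 call held without any single array. Its day 2 call was lost without E2F3 +/- day 2 replicate 1 (adjusted p = 0.0611) or E2F3 +/- lactation replicate 2. Its day 4 call was lost without E2F3 +/- day 4 replicate 1 (adjusted p = 0.0737).

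Of 9 acute phase genes, 9, 8, 6 and 8 were higher at days 1, 2, 3 and 4 in E2F3 +/- glands, the same adjusted over the list alone. For days 1 and 2 camera adjusted p = 6.43e-04 and 0.00159, and adjusted p = 0.102 and 0.141 with an estimated correlation. For days 3 and 4 camera adjusted p = 0.0431 and 0.0416, and adjusted p = 0.422 and 0.491 with an estimated correlation. The day 3 and day 4 calls were also lost without E2F3 +/- lactation replicate 3. So was day 3 without its replicate 1 (adjusted p = 0.0974) and day 4 without its replicate 3 (adjusted p = 0.166). Of 22 milk lipid genes, 0 were higher and 16 lower at day 1, with mean log2 -2.28. Camera on milk lipid genes gave adjusted p = 1.16e-08, adjusted p = 0.0341 with an estimated correlation. On day 2, 0 were higher and 15 lower (0 and 18 adjusted over the list alone) (camera adjusted p = 3.81e-07, adjusted p = 0.0743 with an estimated correlation). On day 3, 1 was higher and 15 lower (camera adjusted p = 5.09e-05, adjusted p = 0.227 with an estimated correlation). On day 4, 2 were higher and 14 lower (camera adjusted p = 0.00104, adjusted p = 0.491 with an estimated correlation).

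Of 7 milk protein genes in E2F3 +/- glands, 1 was higher and 0 lower at day 1. At day 2, 0 were higher and 2 lower (0 and 1 adjusted over the list alone), at day 3, 0 were higher and 5 lower, and at day 4, 0 were higher and 6 lower (camera adjusted p = 0.0416, adjusted p = 0.530 with an estimated correlation). The day 4 list call was lost without E2F3 +/- day 4 replicate 2 (adjusted p = 0.0896). Of 11 macrophage genes, 2, 9, 11 and 11 were higher on days 1 to 4. Their mean was 1.55 at day 2 (camera adjusted p = 0.0140, adjusted p = 0.522 with an estimated correlation) and 2.52 at day 4 (camera adjusted p = 0.00311, adjusted p = 0.491 with an estimated correlation). Of 20 fibroblast genes, 9, 15, 17 and 17 were higher (9, 16, 17 and 17 adjusted over the list alone). At day 4 the fibroblast list had camera adjusted p = 0.00367, adjusted p = 0.530 with an estimated correlation. Beside them, 0, 2, 7 and 3 of 9 skeletal muscle genes were higher (0, 0, 7 and 3 adjusted over the list alone). Of 76 list and day tests, camera called 27 in E2F3 +/- and 25 in wild type glands. With an estimated correlation 1 and 2 remain.

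In E2F3 +/- glands 2183 of 5010 probes passed, 1164 higher and 1019 lower, at day 1 (as deposited 1325 of 2195 higher). At day 2 it was 2298 (1188 higher and 1110 lower), at day 3 3349 (1713 and 1636) and at day 4 3534 (1662 and 1872, as deposited 2029 of 3598 higher). The F test passed 3862. Array quality weights give 3500 at day 1 and 3670 at day 2.

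At day 4 Fabp3 was lower and Igfbp5 higher than at lactation in both genotypes. Over 5010 probes, which are not independent replicates, the log2 changes correlated at r = 0.824, 0.837, 0.850 and 0.854 on days 1 to 4. Of the probes passing in both, 1336 of 1343, 1846 of 1849, 1683 of 1691 and 2403 of 2404 had the same direction.

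Along the involution score, a sum over the probes on all arrays, wild type glands reached 0.525 ± 0.0620 (SD) at day 1 and 1.04 ± 0.185 at day 2. At day 3 they stood at 0.744 ± 0.0563, lower than at day 2, and at day 4 at 0.936 ± 0.0345. E2F3 +/- glands reached 0.615 ± 0.0644, 0.686 ± 0.0307, 0.937 ± 0.223 and 1.06 ± 0.275 on the same days. At lactation the means were 0.0257 and -0.0257. The E2F3 +/- minus wild type difference was -0.0514 at lactation and 0.0898, -0.352, 0.193 and 0.128 on days 1 to 4. Exact permutation gave p = 0.1 at lactation and p = 0.2, 0.1, 0.4 and 0.4 on days 1 to 4, where 0.1 is the smallest it can give. The mean over the 5 times was 0.00148 (permutation p = 0.979). The score is blind to differences off the course it measures.

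**Figure D3:**
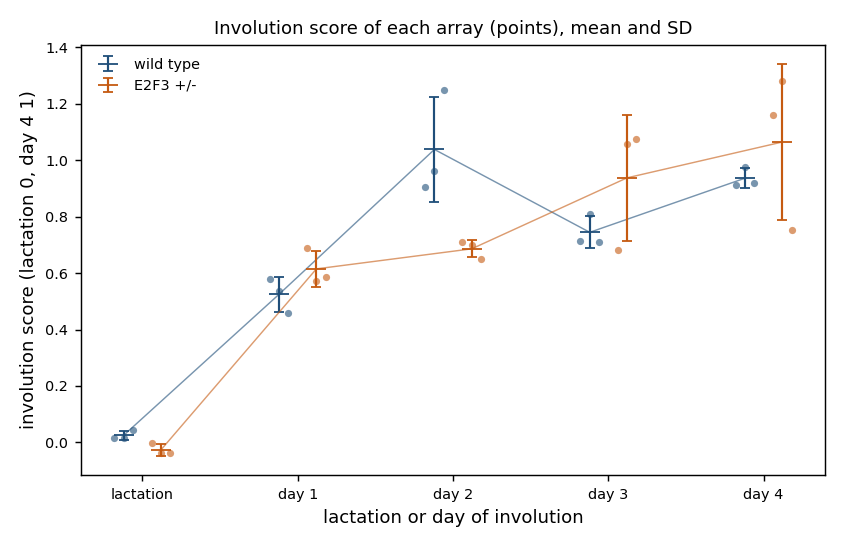
Involution score without unit (vertical, lactation 0 and day 4 1) at lactation and days 1 to 4 (horizontal) in wild type and E2F3 +/- glands, with a point per array and the mean and SD of 3. Wild type glands at day 2 average 1.04 and E2F3 +/- glands 0.686.

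In lactating glands few genes separated the genotypes. The mitochondrial aminopeptidase Metap1d was 3.40-fold higher in E2F3 +/- glands (log2 1.77 ± 0.35, adjusted p = 0.0121, n = 3 and 2). The stress kinase Sgk1 (3.49-fold, log2 -1.80 ± 0.37), the actin regulator Evl (3.39-fold), the aggrecanase Adamts5 (3.18-fold, log2 -1.67 ± 0.31) and the collagen Col16a1 (3.03-fold) were lower. Metap1d lost its call without wild type lactation replicate 3 (adjusted p = 0.154), wild type lactation replicate 2 or E2F3 +/- lactation replicate 3. Sgk1 lost it without E2F3 +/- lactation replicate 3 (adjusted p = 0.179) or wild type lactation replicate 1. Evl lost it without wild type lactation replicate 1 (adjusted p = 0.137), E2F3 +/- lactation replicate 2 or 3. Col16a1 lost it without E2F3 +/- lactation replicate 2 (adjusted p = 0.188), wild type lactation replicate 1 or 2. The Adamts5 probe kept its call without any single array, but adjusted over genes the call was lost without any array but wild type lactation replicate 2 and E2F3 +/- lactation replicate 1 (adjusted p up to 0.107). With limma 19 of 5010 probes passed, 11 higher and 8 lower, of which 12 have no single gene symbol. At unadjusted p under 0.05 there were 374. The count is 12 without E2F3 +/- lactation replicate 3, 45 with the floor of 0.1, 40 with only the groups compared 275 with array quality weights and 46 without the 3 arrays of lowest weight (wild type day 2 replicate 3, E2F3 +/- day 3 replicate 1 and E2F3 +/- day 4 replicate 3).

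Several lists lay slightly lower in E2F3 +/- glands at lactation. Of 11 macrophage genes, 0 were higher and 0 lower (0 and 1 adjusted over the list alone), with mean log2 -0.60. For macrophage genes camera adjusted p = 0.0499, adjusted p = 0.676 with an estimated correlation. Of 7 MHC class II genes, 0 were higher and 0 lower (1 and 2 adjusted over the list alone), with mean log2 -0.52. The MHC class II list had camera adjusted p = 0.0267, adjusted p = 0.676 with an estimated correlation. Of 20 fibroblast genes, 0 were higher and 0 lower (0 and 2 adjusted over the list alone), with mean log2 -0.49. Camera on fibroblast genes gave adjusted p = 0.0267, adjusted p = 0.676 with an estimated correlation. Of 22 milk lipid genes, 0 were higher and 0 lower (0 and 2 adjusted over the list alone), with mean log2 -0.41. For milk lipid genes camera adjusted p = 0.0267, adjusted p = 0.676 with an estimated correlation. Skeletal muscle genes had mean 1.61, and 0 passed. The macrophage call was lost without any array but wild type lactation replicate 2 and E2F3 +/- lactation replicate 1 (adjusted p up to 0.308). The MHC class II call was lost without wild type lactation replicate 1 (adjusted p = 0.0687). The fibroblast call was lost without wild type lactation replicate 1 (adjusted p = 0.344) or E2F3 +/- lactation replicate 3. The milk lipid call was lost without E2F3 +/- lactation replicate 1 (adjusted p = 0.0575) or wild type lactation replicate 2.

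At day 1 the aminopeptidase Anpep was 4.39-fold higher in E2F3 +/- glands (log2 2.13 ± 0.31, adjusted p = 0.00212) and kept its call without any single array. The oxidoreductases Cyp2e1 (7.02-fold, log2 2.81 ± 0.65) and Cbr2 (4.61-fold) and the fatty acid carrier Slc27a1 (4.03-fold) were higher too. Lower were Mt2 (6.21-fold, log2 -2.63 ± 0.57), the small heat shock protein Hspb1 (4.87-fold), the leukocyte adaptor Cytip (3.94-fold) and the luminal keratin Krt8 (3.47-fold). Cyp2e1 lost its call without any array but wild type day 1 replicate 3 (adjusted p up to 0.198). Cbr2 lost it without any array but E2F3 +/- day 1 replicate 1 (adjusted p up to 0.147). Slc27a1 lost it without any array but E2F3 +/- day 1 replicate 2 (adjusted p up to 0.189). Mt2 lost it without any array but E2F3 +/- day 1 replicate 1 (adjusted p up to 0.222). Hspb1 lost it without any array but wild type day 1 replicate 2 (adjusted p up to 0.256). Krt8 lost it without any array but wild type day 1 replicate 2 and E2F3 +/- day 1 replicate 1 (adjusted p up to 0.147). Cytip lost it without E2F3 +/- day 1 replicate 3 (adjusted p = 0.0820) or wild type day 1 replicate 1.

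Of 22 milk lipid genes, 0 were higher and 0 lower (2 and 0 adjusted over the list alone) in E2F3 +/- glands at day 1, with mean log2 0.65. The milk lipid list had camera adjusted p = 3.77e-04, adjusted p = 0.425 with an estimated correlation. Of 20 fibroblast genes, 0 were higher and 0 lower, with mean log2 0.49. Camera on fibroblast genes gave adjusted p = 0.00408, adjusted p = 0.524 with an estimated correlation. That call was lost without E2F3 +/- day 1 replicate 3 (adjusted p = 0.177). Of 10 luminal genes, 0 were higher and 1 lower (0 and 2 adjusted over the list alone), with mean log2 -0.81. For luminal genes camera adjusted p = 0.00556, adjusted p = 0.524 with an estimated correlation. Skeletal muscle genes had mean 1.38, and 0 passed. In limma 33 of 5010 probes passed, 17 higher and 16 lower. The count is 1 without E2F3 +/- day 1 replicate 3, 12 without its replicate 1, and 2 and 8 without wild type day 1 replicates 1 and 3. It is 2 with only the groups compared, 18 with the floor of 0.1, 103 with quantile normalization 239 with array quality weights and 127 without those 3 arrays of lowest weight. The muscle list as a covariate gives 67.

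At day 2 Lalba, a whey protein of milk, was 10.3-fold higher in E2F3 +/- glands (log2 3.36 ± 0.65, adjusted p = 0.00257). Xdh, which coats milk fat, was 7.94-fold higher (log2 2.99 ± 0.61), and the acute phase carrier Orm2 49.0-fold (log2 5.61 ± 1.201). The macrophage lysozymes Lyz1 (10.9-fold, log2 -3.44 ± 0.62) and Lyz2 (10.7-fold, log2 -3.42 ± 0.65), the phagocyte glycoprotein Gpnmb (7.49-fold) and the inhibitory receptor Lilrb4a (6.47-fold) were lower. The vesicle protein Rab15 (21.2-fold, n = 3 and 2), the amino acid oxidase Lao1 (18.9-fold) and the epithelial protease Tmprss2 (18.1-fold) were higher. Lao1 lost its call without E2F3 +/- day 2 replicate 3 (adjusted p = 0.0617) or wild type day 2 replicate 2. Tmprss2 lost its call without any array but wild type day 2 replicate 1 and E2F3 +/- day 2 replicate 1 (adjusted p up to 0.0670). Of 7 milk protein genes, 5 were higher and 0 lower (6 and 0 adjusted over the list alone), with mean log2 2.34. The milk protein list had camera adjusted p = 3.37e-04, adjusted p = 0.311 with an estimated correlation. Among them, Csn3 (1.68 ± 0.49) lost its call without wild type day 2 replicate 2 (adjusted p = 0.109), E2F3 +/- day 2 replicate 2 or 3. Likewise Folr1 (2.66 ± 0.74) lost its call without any array but wild type day 2 replicate 1 and E2F3 +/- day 2 replicate 1 (adjusted p up to 0.0902).

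Of 11 macrophage genes, 0 were higher and 8 lower (0 and 11 adjusted over the list alone) in E2F3 +/- glands at day 2, with mean log2 -1.95. Camera on macrophage genes gave adjusted p = 8.53e-06, adjusted p = 0.267 with an estimated correlation. The receptor chain Tyrobp (-1.64 ± 0.27) is among them. Matrix proteases, which open the basement membrane of the gland, were lower as well: Mmp14 (-2.11 ± 0.41), Mmp11 (-2.10 ± 0.45), Mmp2 (-1.85 ± 0.33) and Adamts5 (-1.88 ± 0.32). Of 7 matrix protease genes, 0 were higher and 5 lower, with mean log2 -1.12. For matrix protease genes camera adjusted p = 0.00514, adjusted p = 0.267 with an estimated correlation. Antigen presentation genes such as Ctss (-2.32 ± 0.48) and Cd74 (-1.23 ± 0.29) were lower. Of 7 MHC class II genes, 0 were higher and 3 lower (0 and 5 adjusted over the list alone), with mean log2 -0.94. The MHC class II list had camera adjusted p = 0.00514, adjusted p = 0.315 with an estimated correlation. That call was lost without wild type day 2 replicate 2 (adjusted p = 0.0565). Of the matrix genes, Lum (-2.28 ± 0.51), Fbln1 (-2.27 ± 0.42) and Dcn (-1.83 ± 0.30) were lower. Of 20 fibroblast genes, 1 was higher and 4 lower (1 and 8 adjusted over the list alone), with mean log2 -0.82. Camera on fibroblast genes gave adjusted p = 0.00868, adjusted p = 0.482 with an estimated correlation. Skeletal muscle genes had mean -0.49, and 0 passed.

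The interferon factor Irf1 (-1.73 ± 0.34) and the respiratory chain gene Ndufa5 (-1.10 ± 0.34) were lower at day 2, and the epithelial factor Elf3 (1.505 ± 0.34) was higher. Of 7 interferon genes, 0 were higher and 3 lower (0 and 5 adjusted over the list alone), with mean log2 -1.19. For interferon genes camera adjusted p = 0.0217, adjusted p = 0.435 with an estimated correlation. Of 25 oxidative phosphorylation genes, 0 were higher and 3 lower (0 and 5 adjusted over the list alone), with mean log2 -0.62. The oxidative phosphorylation list had camera adjusted p = 6.87e-04, adjusted p = 0.482 with an estimated correlation. Of 10 luminal genes, 3 were higher and 0 lower (4 and 0 adjusted over the list alone), with mean log2 0.89. Camera on luminal genes gave adjusted p = 0.0311, adjusted p = 0.435 with an estimated correlation. The fibroblast, interferon and luminal calls were lost without wild type day 2 replicate 2 or without E2F3 +/- day 2 replicate 3 (adjusted p up to 0.163, 0.177 and 0.555). Ndufa5 lost its call without any array but wild type day 2 replicate 2 and E2F3 +/- day 2 replicate 1 (adjusted p up to 0.190). Lum lost its call without E2F3 +/- day 2 replicate 3 (adjusted p = 0.0610).

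Other acute phase genes such as Lcn2 (1.61 ± 0.38) were higher at day 2 (4 higher and 0 lower), though the list did not pass (camera adjusted p = 0.0654). Stat3, an effector of involution, was higher (1.75 ± 0.51), as was the chaperone Clu (1.70 ± 0.48). The replication clamp Pcna (-1.08 ± 0.26) was lower. Lcn2 and Pcna lost their calls without E2F3 +/- day 2 replicate 3 (adjusted p = 0.0723 and 0.0610). Stat3 lost its call without wild type day 2 replicate 3 (adjusted p = 0.119) or E2F3 +/- day 2 replicate 3. Clu lost its call without E2F3 +/- day 2 replicate 3 (adjusted p = 0.127) or wild type day 2 replicate 2. Lyz1, Lyz2, Gpnmb, Tyrobp, Lalba, Xdh, Orm2, Irf1, Elf3, Dcn, Fbln1, Ctss, Cd74, Adamts5 and the 3 Mmp genes kept their calls without any single array.

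In limma 638 of 5010 probes passed, 359 higher and 279 lower, in E2F3 +/- glands at day 2. As deposited, without centring, 693 pass with 294 higher, so the larger share turns to lower. The count is 364, 348 and 129 without E2F3 +/- day 2 replicates 1, 2 and 3, and 314 without wild type day 2 replicate 3. It is 290 with array quality weights, 302 with only the groups compared and 411 with the floor of 0.1. Day 2 has the highest genotype count as fitted, but array quality weights give more at day 3 (863) and day 4 (1050). Set against wild type day 3 glands instead, E2F3 +/- day 2 glands differed at 15 probes (632 at unadjusted p under 0.05). E2F3 +/- day 3 glands differed from wild type day 2 glands at 0 (738 at unadjusted p under 0.05, limma). These comparisons across days were chosen after the scores were seen.

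At day 3 0 probes passed in limma, with 691 at unadjusted p under 0.05. The nearest were the apoptosis gene Shisa5 (log2 -1.80 ± 0.34, adjusted p = 0.107), the lysosomal Idua (1.69 ± 0.36, adjusted p = 0.296, n = 2 and 3) and Ttc5 (1.13 ± 0.26, adjusted p = 0.299). Without E2F3 +/- day 3 replicate 1, 365 probes pass, and without wild type day 3 replicate 1, 1. Array quality weights give 863, leaving out the 3 arrays of lowest weight 1143, and the floor of 0.1 gives 4. Skeletal muscle genes had mean 1.97, and 0 passed.

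At day 4 the translation factor Eif4g3 was 2.95-fold higher in E2F3 +/- glands (log2 1.56 ± 0.32, adjusted p = 0.0184). The repressor Zfp503 (2.79-fold), Vwa5a (2.37-fold) and the microtubule regulator Stmn1 (2.11-fold) were higher. The keratin Krt84 (8.93-fold, log2 -3.16 ± 0.59), Gpnmb (5.43-fold) and the translation kinase Mknk2 (5.27-fold) were lower. Each of these calls depends on single arrays. Eif4g3 is lost without E2F3 +/- day 4 replicate 1 (adjusted p = 0.111), wild type day 4 replicate 1 or E2F3 +/- day 4 replicate 2. Zfp503 is lost without wild type day 4 replicate 1 (adjusted p = 0.0759) or E2F3 +/- day 4 replicate 2. Vwa5a is lost without any array but wild type day 4 replicate 3 and E2F3 +/- day 4 replicate 3 (adjusted p up to 0.160). Stmn1 is lost without any array but wild type day 4 replicate 2 and E2F3 +/- day 4 replicate 3 (adjusted p up to 0.161). Krt84 is lost without E2F3 +/- day 4 replicate 1 (adjusted p = 0.0820) or E2F3 +/- day 4 replicate 2. Gpnmb is lost without any array but E2F3 +/- day 4 replicate 1 and 3 (adjusted p up to 0.128). Mknk2 is lost without any array but E2F3 +/- day 4 replicate 3 (adjusted p up to 0.285).

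Of 21 lysosome genes, 0 were higher and 0 lower (0 and 4 adjusted over the list alone) at day 4, with mean log2 -0.59. For lysosome genes camera adjusted p = 0.0245, adjusted p = 0.911 with an estimated correlation. That call was lost without E2F3 +/- day 4 replicate 2 (adjusted p = 0.156), wild type day 4 replicate 2 or E2F3 +/- day 4 replicate 3. Of 22 milk lipid genes, 0 were higher and 0 lower (0 and 4 adjusted over the list alone), with mean log2 -0.60. The milk lipid list had camera adjusted p = 0.0245, adjusted p = 0.911 with an estimated correlation. That call was lost without any array but wild type day 4 replicate 1 and E2F3 +/- day 4 replicate 1 (adjusted p up to 0.156). Of the macrophage genes 0 were higher and 0 lower (0 and 3 adjusted over the list alone). Skeletal muscle genes had mean -0.36, and 0 passed. In limma 56 of 5010 probes passed, 9 higher and 47 lower. The count is 3, 1 and 777 without E2F3 +/- day 4 replicates 1, 2 and 3. It is 5, 35 and 17 without wild type day 4 replicates 1, 2 and 3. Only the groups compared gives 0, quantile normalization 23 (6 higher), the floor of 0.1 27, array quality weights 1050, leaving out the 3 arrays of lowest weight 1261 and the muscle list as a covariate 491.

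Averaged over the 5 times, the galactose-binding macrophage protein Lgals3 was 2.28-fold lower in E2F3 +/- glands (log2 -1.19 ± 0.21, adjusted p = 0.00571). The dynein chain Dynlt1b (1.65-fold, log2 0.72 ± 0.13) and Metap1d (1.63-fold, log2 0.70 ± 0.14) were higher. These 3 calls held without any single array. Ctsl (1.73-fold) and the phospholipase Pnpla7 (1.54-fold) were also higher, and Lilrb4a (2.02-fold), the leukocyte formin Fmnl1 (1.82-fold) and the lipid carrier Pltp (1.65-fold) lower. Ctsl was lost without any of 21 of the 30 arrays (adjusted p up to 0.0880, without wild type day 1 replicate 2). Left out singly, 19 and 20 of the 30 arrays ended the calls of Pnpla7 and Pltp. Their highest adjusted p was 0.0804 and 0.0913, without E2F3 +/- day 2 replicate 3. Likewise 18 and 14 ended those of Lilrb4a and Fmnl1 (adjusted p up to 0.113 and 0.105, without wild type lactation replicate 1).

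Of 11 macrophage genes, 0 were higher and 0 lower (0 and 10 adjusted over the list alone) over all times, with mean log2 -0.71. Camera on macrophage genes gave adjusted p = 1.95e-07, adjusted p = 0.134 with an estimated correlation. Of 7 matrix protease genes, 0 were higher and 1 lower (0 and 5 adjusted over the list alone), with mean log2 -0.47. For matrix protease genes camera adjusted p = 0.00190, adjusted p = 0.134 with an estimated correlation. The member passing, Adamts5, lost its call without any of 22 of the 30 arrays (adjusted p up to 0.0900, without E2F3 +/- day 2 replicate 3). Of 7 MHC class II genes, 0 were higher and 0 lower (0 and 3 adjusted over the list alone), with mean log2 -0.33. The MHC class II list had camera adjusted p = 0.00190, adjusted p = 0.256 with an estimated correlation. Of 7 milk protein genes, 0 were higher and 0 lower (3 and 0 adjusted over the list alone), with mean log2 0.37. Camera on milk protein genes gave adjusted p = 0.0452, adjusted p = 0.647 with an estimated correlation. The milk protein call was lost without any of 12 of the 30 arrays (adjusted p up to 0.355, without E2F3 +/- day 4 replicate 3). Of 9 skeletal muscle genes, 0 were higher and 0 lower (1 and 0 adjusted over the list alone), with mean 0.82. Over all times 31 of 5010 probes passed, 20 higher and 11 lower in limma, and 661 had an unadjusted p under 0.05. The count is 19 without wild type lactation replicate 1, 47 and 91 without wild type day 2 replicates 1 and 3. It is 20 without wild type day 3 replicate 2. Without E2F3 +/- replicate 3 of lactation and days 1 to 4 it is 20, 20, 20, 56 and 133. Quantile normalization gives 48 (39 higher), array quality weights 491, leaving out the 3 arrays of lowest weight 1087 and the muscle list as a covariate 52.

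Where the genotypes' responses were tested against each other, the collagen Col16a1 came first (F test adjusted p = 4.52e-04). Its E2F3 +/- response exceeded the wild type response by log2 2.58 ± 0.45 at day 1 (adjusted p = 0.00534) and 2.33 ± 0.45 at day 3 (adjusted p = 0.0116). The day 3 call was lost without wild type day 3 replicate 3 (adjusted p = 0.0629), E2F3 +/- lactation replicate 2 or E2F3 +/- day 3 replicate 2. The tetraspanin Cd9 (F test adjusted p = 0.00294) differed most at day 2 (log2 1.63 ± 0.34), without passing on that day alone (adjusted p = 0.0653). Likewise Zfp503 (F test adjusted p = 0.00608) differed most at day 4 (1.39 ± 0.41, adjusted p = 0.161). Cotl1, which binds actin (F test adjusted p = 0.00904), differed most at day 2 (-1.18 ± 0.33, adjusted p = 0.109).

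The aggrecanase Adamts5 (F test adjusted p = 0.00671) differed at day 3 (log2 2.11 ± 0.44, adjusted p = 0.0323). Adamts5 lost this call without any array but E2F3 +/- day 3 replicate 1 (adjusted p up to 0.153). The heme-binding Hebp1 (F test adjusted p = 0.00904) differed at day 1 (2.88 ± 0.57, adjusted p = 0.0167). Hebp1 lost this call without any of 7 of the 12 arrays (adjusted p up to 0.0770, without wild type day 1 replicate 3). In limma the F test passed 303 probes (1561 at unadjusted p under 0.05), of which 89 have no single gene symbol. Passing on days 1 to 4 were 19, 0, 12 and 16 (411, 822, 435 and 547 at unadjusted p under 0.05). The F test count is 159, 172 and 166 without wild type lactation replicates 1, 2 and 3, 148, 193 and 148 without wild type day 1 replicates 1, 2 and 3, 502, 465 and 121 without wild type day 2 replicates 1, 2 and 3, 137, 136 and 124 without wild type day 3 replicates 1, 2 and 3, 146 without wild type day 4 replicate 3, 176, 145 and 147 without E2F3 +/- lactation replicates 1, 2 and 3, 149, 158 and 154 without E2F3 +/- day 1 replicates 1, 2 and 3, 88, 105 and 53 without E2F3 +/- day 2 replicates 1, 2 and 3, 1112 and 143 without E2F3 +/- day 3 replicates 1 and 3, 150 and 1343 without E2F3 +/- day 4 replicates 1 and 3. It is 179 with replicate number as a block, 121 with the floor of 0.1, 466 with quantile normalization, 2399 with array quality weights and 1752 without the 3 arrays of lowest weight.

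Several lists answered day 1 differently in the genotypes. For milk lipid the mean difference was 1.06, with 0 higher and 0 lower (8 and 0 adjusted over the list alone) and camera adjusted p = 1.48e-06, adjusted p = 0.102 with an estimated correlation. For fibroblasts it was 0.98, with 0 higher and 0 lower (3 and 0 adjusted over the list alone) and camera adjusted p = 4.01e-05, adjusted p = 0.314 with an estimated correlation. For luminal genes it was -0.84, with 0 higher and 0 lower (0 and 1 adjusted over the list alone) and camera adjusted p = 0.00264, adjusted p = 0.314 with an estimated correlation. For MHC class II it was 0.82, with 0 higher and 0 lower (0 and 0 adjusted over the list alone) and camera adjusted p = 0.0131, adjusted p = 0.314 with an estimated correlation. For adipocytes it was 1.53, with 0 higher and 0 lower (1 and 0 adjusted over the list alone) and camera adjusted p = 0.0131, adjusted p = 0.314 with an estimated correlation. For acute phase genes it was 1.59, with 0 higher and 0 lower (0 and 0 adjusted over the list alone) and camera adjusted p = 0.0406, adjusted p = 0.314 with an estimated correlation. For macrophages it was 0.83, with 0 higher and 0 lower (0 and 0 adjusted over the list alone) and camera adjusted p = 0.0406, adjusted p = 0.447 with an estimated correlation. Most of the macrophage and MHC class II differences lay at lactation, where E2F3 +/- glands were lower. The adipocyte call was lost without wild type day 1 replicate 2 (adjusted p = 0.0612). The acute phase call was lost without any of 8 of the 12 arrays (adjusted p up to 0.125, without wild type day 1 replicate 3). The macrophage call was lost without any of 6 of the 12 arrays (adjusted p up to 0.123, without wild type lactation replicate 1).

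At day 2 the mean difference for milk proteins was 2.59, with 0 higher and 0 lower (5 and 0 adjusted over the list alone) and camera adjusted p = 5.63e-04, adjusted p = 0.466 with an estimated correlation. Acute phase genes had 2.21, with 0 higher and 0 lower (6 and 0 adjusted over the list alone) and camera adjusted p = 0.0149, adjusted p = 0.466 with an estimated correlation. Macrophage genes had -1.35, with 0 higher and 0 lower (0 and 5 adjusted over the list alone) and camera adjusted p = 0.00135, adjusted p = 0.466 with an estimated correlation. Respiratory genes had -0.65, with 0 higher and 0 lower (0 and 0 adjusted over the list alone) and camera adjusted p = 2.32e-04, adjusted p = 0.640 with an estimated correlation. Without wild type day 2 replicate 2 the acute phase and macrophage calls were lost (adjusted p = 0.0525 and 0.127). Skeletal muscle genes had mean -0.23 at day 1 and -2.11 at day 2, and 0 passed.

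Genes that E2F factors drive showed no genotype difference as a list. Of 9 E2F targets, which build the replication machinery, 1 higher and 3 lower (2 and 4 adjusted over the list alone), 5 and 3, 3 and 4 and 3 and 4 passed on days 1 to 4 in wild type glands. In E2F3 +/- glands it was 3 higher and 2 lower, 3 and 2, 4 and 4 (5 and 4 adjusted over the list alone) and 4 and 2. No camera call was made at any time. Chromatin assembly genes Chaf1a (-2.24 ± 0.45) and Chaf1b (-2.20 ± 0.37, n = 2 and 2) fell by day 4, and the helicase Mcm7 (1.55 ± 0.31) rose at day 2. Between genotypes only Pcna passed, at day 2 (camera adjusted p = 0.525 for the list). Of 3 mitosis genes, 0 higher and 1 lower, 1 and 0, 0 and 1 and 0 and 2 passed in wild type glands. For 3 genes of the E2F and retinoblastoma family it was 0 higher and 0 lower, 1 and 1, 0 and 1 and 1 and 1. Between genotypes 0 of either list passed in limma at any time.

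Of 7 Stat3 and LIF genes, among them Osmr and Igfbp5, 4 higher and 0 lower (4 and 1 adjusted over the list alone), 3 and 1, 4 and 0 and 4 and 2 passed on days 1 to 4 in wild type glands. For 9 TGF-beta genes it was 5 higher and 0 lower, 5 and 0, 7 and 0 and 5 and 0. Of 8 apoptosis genes, 1 higher and 2 lower, 0 and 2 (0 and 1 adjusted over the list alone), 1 and 1 and 0 and 1 (0 and 0 adjusted over the list alone) passed. These lists have too few genes on all arrays for camera. The effector Bak1 (1.56 ± 0.51) was higher at day 1 and Diablo (-0.82 ± 0.29) lower at day 4. Bak1 lost its call without wild type day 1 replicate 1 (adjusted p = 0.0570), wild type lactation replicate 2 or wild type day 1 replicate 3. Diablo lost its call without wild type lactation replicate 2 (adjusted p = 0.0756), wild type lactation replicate 3 or wild type day 4 replicate 1. Matrix proteases, with Mmp3 (1.63 ± 0.39) and Adamts5 (-4.62 ± 0.32) in front, counted 1 higher and 1 lower, 4 and 1, 4 and 1 and 4 and 1 of 7. Adipocyte genes counted 0 higher and 2 lower, 6 and 2, 4 and 2 (5 and 2 adjusted over the list alone) and 5 and 2 of 9. Interferon genes counted 1 higher and 1 lower (2 and 1 adjusted over the list alone), 6 and 1, 3 and 1 and 4 and 1 of 7. MHC class II genes counted 0 higher and 1 lower, 4 and 1, 4 and 0 and 5 and 1 of 7. None of these 4 lists had a camera call in wild type involution.

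Unfolded protein response genes counted 0 higher and 2 lower (0 and 1 adjusted over the list alone), 5 and 3, 2 and 1 and 2 and 2 of 11 in wild type glands. Immediate early genes counted 4 higher and 2 lower, 5 and 1, 5 and 1 and 5 and 1 of 8. Endothelial genes counted 1 higher and 0 lower, 3 and 0, 0 and 0 and 0 and 0 of 5. None of these had a camera call. Myoepithelial genes counted 0 higher and 0 lower, 2 and 2, 2 and 0 and 2 and 1 of 4, and 2 higher and 0 lower between genotypes at day 2, without a camera test. The chemokine Ccl5, the only T and NK cell gene tested, counted 0 higher and 1 lower at day 1 and 0 higher and 1 lower between genotypes at day 2. The antibody joining chain Jchain, the only B and plasma cell gene tested, counted 1 higher and 0 lower at day 2 and 1 higher and 0 lower at day 4.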

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

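The contrast of the day 2 genotype difference with the other 4 times, the score difference over days 1 to 3, the exchange of the wild type labels and the counts under other splits of the arrays were chosen only after results had been seen.

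Several genes answered involution differently in the 2 genotypes. As E2F3 +/- response minus wild type response, Col16a1 differed by log2 2.58 and Hebp1 by 2.88 at day 1, Cd9 by 1.63 and Cotl1 by -1.18 at day 2, Adamts5 by 2.11 at day 3 and Zfp503 by 1.39 at day 4. Milk lipid genes differed by 1.06 at day 1, with acute phase genes 1.59, adipocyte genes 1.53, fibroblast genes 0.98, macrophage genes 0.83, MHC class II genes 0.82 and luminal genes -0.84. At day 2 milk proteins differed by 2.59, acute phase genes by 2.21, respiratory genes by -0.65 and macrophage genes by -1.35. In these lists 0 members pass over all genes, and with an estimated correlation 0 of the 11 list calls remain. Genotype by time passed 303 probes in the F test, 19 at day 1, 0 at day 2, 12 at day 3 and 16 at day 4. The day 2 difference set against the other 4 times passed 1136.

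The genotype difference at day 2, with macrophage genes (Lyz2) low and milk genes (Lalba) high in E2F3 +/- glands, was weighed against 3 explanations. Muscle content stays open: 845 probes pass with the muscle list mean as covariate. That fit leans on E2F3 +/- day 4 (muscle SD 4.27, others up to 1.82). Slower involution of the E2F3 +/- glands stays open: the mean score difference over days 1 to 3 is -0.0231 (permutation p = 0.793). Exchanged labels of the wild type day 2 and day 3 glands may account for the difference, since at most 15 probes then differ at either day. Wild type day 2 glands truly further along would give the same count, and the day 3 count is 0 as labelled. So a labelling error and biology are not told apart.

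The first 2 explanations written down for this difference were set aside after their values had been seen, and the exchange of labels took their place. They were that wild type day 2 replicate 3 alone carried the difference, where 314 probes pass without it, and that this array had been swapped with E2F3 +/- day 4 replicate 3. The latter array correlates at r = 0.0792 with the wild type day 2 mean and at 0.376 with the wild type day 3 mean, and the former at 0.873 with the mean of the other E2F3 +/- day 4 arrays.

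Other splits of the same arrays were counted for each comparison, with the real count given against the highest of the others. With 3 against 3 there are 10 splits, too few for a share under 0.05. For wild type against lactation the counts were 1839 against 0, 3267 against 12, 1954 against 0 and 2825 against 11 on days 1 to 4, and for E2F3 +/- 2183 against 1, 2298 against 2, 3349 against 2 and 3534 against 10, each the highest, so 1 of 10. Between genotypes they were 19 against 0 at lactation, 33 against 0 at day 1 and 638 against 46 at day 2, again 1 of 10. At day 3 the count was 0 against 3 (10 of 10 splits reach it), and at day 4 56 against 460 (3 of 10). A mixed split of the day 4 arrays thus separates more probes than genotype, which points to another structure there.

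For the broader tests 100 splits were drawn. The counts were 4108 against 2035 for wild type change over time, 3862 against 2357 for E2F3 +/- change over time, 31 against 7 for genotype over all times, 303 against 10 for genotype by time and 1136 against 431 for day 2 against the other times, each 1 of 100. Chance is argued against for the first 4, at the lowest share 100 splits give. The last was chosen because day 2 stood out, which the splits ignore, so it is left undecided. High counts of other splits in both tests over time and the last contrast show structure among the arrays too.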

How the results depend on the processing

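Among results with a call a single sign turned. Csn3 at wild type day 3 against lactation is -1.34 on log2 (adjusted p = 0.0285) and 0.346 with quantile normalization. Its call is lost without wild type lactation replicate 1 (adjusted p = 0.138) or 3, or wild type day 3 replicate 1. The cause was not tested. Among named probes, 1663 of 1760 results under other settings stayed called or uncalled, 66 lost a call and 31 gained it. Leaving out arrays gave 1142, 206 and 8 of 1356. Genes named from lists gave 2615, 48 and 108 of 2772, and 2298, 112 and 62 of 2472. For called lists 638 were kept and 145 lost of 783, and 682 and 74 of 756.

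With replicate number as a block (replicate block), genotype by time passes 179 probes instead of 303, and it changed no other call by more than 1.5-fold; replicate numbers show no pairing between groups.

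With quantile normalization, these counts moved by more than 1.5-fold: genotype at day 1 103 (from 33), genotype at day 4 23 (from 56), genotype over all times 48 (from 31), genotype by time 466 (from 303), lists called in genotype by time 7 (from 11).

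With array quality weights, these counts moved by more than 1.5-fold: wild type day 1 3005 (from 1839), wild type day 3 3487 (from 1954), E2F3 +/- day 1 3500 (from 2183), E2F3 +/- day 2 3670 (from 2298), genotype at lactation 275 (from 19), genotype at day 1 239 (from 33), genotype at day 2 290 (from 638), genotype at day 3 863 (from 0), genotype at day 4 1050 (from 56), genotype over all times 491 (from 31), genotype by time 2399 (from 303).

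With only the groups compared, these counts moved by more than 1.5-fold: wild type day 3 3209 (from 1954), genotype at lactation 40 (from 19), genotype at day 1 2 (from 33), genotype at day 2 302 (from 638), genotype at day 4 0 (from 56).

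With a floor of 0.1 and all probes, these counts moved by more than 1.5-fold: genotype at lactation 45 (from 19), genotype at day 1 18 (from 33), genotype at day 2 411 (from 638), genotype at day 3 4 (from 0), genotype at day 4 27 (from 56), genotype by time 121 (from 303).

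Without the 3 arrays of lowest quality weight, these counts moved by more than 1.5-fold: genotype at lactation 46 (from 19), genotype at day 1 127 (from 33), genotype at day 3 1143 (from 0), genotype at day 4 1261 (from 56), genotype over all times 1087 (from 31), genotype by time 1752 (from 303).

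With an estimated correlation, these counts moved by more than 1.5-fold: lists called in wild type 2 (from 25), lists called in E2F3 +/- 1 (from 27), lists called between genotypes 0 (from 21), lists called in genotype by time 0 (from 11). The 3 arrays of lowest weight are E2F3 +/- day 4 replicate 3 (0.143), wild type day 2 replicate 3 (0.165), E2F3 +/- day 3 replicate 1 (0.290). The cause of these shifts was not tested.

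Leaving out 1 array at a time gave these lowest and highest counts, with that on all arrays in brackets. Wild type day 1 1373 to 1629 (1839), wild type day 2 2801 to 3184 (3267), wild type day 3 1377 to 1616 (1954), wild type day 4 2267 to 2482 (2825), wild type over time 3680 to 4127 (4108), genotype at lactation 12 to 24 (19), genotype over all times 19 to 133 (31), genotype by time 53 to 1343 (303), genotype by time at day 1 8 to 17 (19), genotype by time at day 2 0 to 24 (0). Genotype by time at day 3 9 to 74 (12), genotype by time at day 4 9 to 283 (16), day 2 against the other times 310 to 1760 (1136), genotype at day 1 1 to 28 (33), genotype at day 2 129 to 780 (638), genotype at day 3 0 to 365 (0), genotype at day 4 1 to 777 (56), E2F3 +/- day 1 1544 to 1787 (2183), E2F3 +/- day 2 1671 to 1943 (2298), E2F3 +/- day 3 2578 to 3399 (3349), E2F3 +/- day 4 2958 to 3701 (3534), E2F3 +/- over time 3198 to 4205 (3862), lists called in wild type 24 to 28 (25), lists called between genotypes 16 to 26 (21), lists called in genotype by time 8 to 14 (11), lists called in E2F3 +/- 23 to 28 (27).

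The mean score difference between genotypes, 0.00148 as fitted, ran from -0.0255 to 0.0359 when 1 array was left out, and from -0.0165 to 0.0822 over the other settings, the latter without the 3 arrays of lowest weight (permutation p = 0.120). The day 2 difference, -0.352 as fitted, was -0.241 without them.

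Scaling moved the share of higher probes by more than 10 points in a few comparisons. As deposited, they were wild type day 3 2027 with 1112 higher (centred 1954 with 873), genotype at day 2 693 with 294 higher (centred 638 with 359), day 2 against the other times 1185 with 564 higher (centred 1136 with 687); with quantile normalization, genotype at lactation 22 with 15 higher (centred 19 with 11), genotype at day 4 23 with 6 higher (centred 56 with 9), genotype over all times 48 with 39 higher (centred 31 with 20), genotype by time at day 1 22 with 8 higher (centred 19 with 9), genotype by time at day 3 18 with 7 higher (centred 12 with 2), day 2 against the other times 1109 with 535 higher (centred 1136 with 687); and with a median over probes on all arrays, genotype over all times 38 with 20 higher (centred 31 with 20). As deposited, the median probe moves by log2 0.05 to 0.29 in the days against lactation. The table gives no intensities, so no background or signal filter was varied.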

Other observations

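The genes listed at 0 or 0.01 throughout lactation, the 9 probes without a symbol, the skeletal muscle scaling values, the falls between neighbouring times and the tests of these were chosen only after values had been seen.

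Some genes were listed at 0 or 0.01 on all 6 lactation arrays and above it on all 6 day 4 arrays. Of 278 probes at that value throughout lactation, 11 did so. They include the myeloid genes Ms4a7 (median ratio at day 4 14.5), Ly86 (6.80) and the inflammasome sensor Nlrp3 (2.06). The vitamin D and sterol hydroxylases Cyp24a1 (4.65) and Cyp27a1 (3.70), the prostaglandin dehydrogenase Hpgd (3.95) and the citrate carrier Slc13a2 (7.95) are among them. The others are the muscle membrane genes Sspn (8.02) and Cacng1 (3.50), the kinase Camk2a (2.89) and a probe without a symbol (1.75). They were not tested, because too few lactation arrays hold a value, and absence at lactation is not shown.

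A set of 9 probes without a gene symbol moved together over the 30 arrays (lowest pairwise r = 0.853, median 0.950). In wild type glands their mean log2 ratio was -2.36 ± 0.22 (SD, n = 3) at lactation and 2.74, -2.56, 0.23 and -1.39 at days 1 to 4. In E2F3 +/- glands it was 4.67 ± 0.60 and then 2.83, 3.17, -0.31 and -2.85. At lactation they were 65.2- to 337-fold higher in E2F3 +/- glands, and all 9 passed (adjusted p = 6.25e-06 to 0.00170, limma).

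For these probes, a sequence tied to the targeted allele is argued against by their rise in wild type day 1 glands (mean 2.74, lactation -2.36). As they were picked for moving together, 9 of 9 higher counts once. A common reference at its lowest value is argued against, with 8.78% of 148 ratios from 1 to 100 whole multiples of 0.1 (tolerance 1e-06 of that step), where chance gives 10% from 10 to 100. A handling or labelling batch that holds whole groups was not decided. Of the variance of their mean, 90.02% lies between groups, but the probes were picked for such differences, and the labels name no batch.

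Skeletal muscle genes varied widely between arrays. Over the 3 measured on all arrays, their mean log2 ratio was -0.09, 0.32, 4.14, 2.58 and 4.11 in wild type and 1.42, 2.02, 3.51, 4.73 and 3.64 in E2F3 +/- glands (n = 3 each). Arrays of a group differed by up to SD 3.24 (E2F3 +/- day 4). Within groups 1151 probes follow the mean of all 9 genes. The fit leans on E2F3 +/- day 4 (0.24 in replicate 3, 6.82 and 8.25 in 1 and 2), so these may mark replicate 3 rather than muscle.

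Skeletal muscle carried with the gland may explain this: the deviations of the muscle genes from their group means correlate pairwise at 0.740 (permutation p = 9.99e-04, the smallest that 1000 shuffles give), at 0.711 by rank and at 0.675 without E2F3 +/- day 4 replicates 3 and 2. In other lists this correlation ran from -0.0147 to 0.526. Unequal scaling between arrays is argued against, since the smaller change at wild type day 4 under other scalings is log2 4.30. Involution time stays open, as the mean of all 9 genes, each centred over the arrays, falls between neighbouring times by at most 1.41 (step of -1.41).

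All 3 E2F3 +/- day 3 arrays lay closer to another group than to their own. Replicate 1 had own r = -0.109 and r = 0.433 to wild type day 3. Replicates 2 and 3 had own r = 0.470 and 0.652, and r = 0.7999 and 0.749 to E2F3 +/- day 4. The share of values at 0 or 0.01 ran from 1.02% to 22.0% over arrays.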
